A study of Homo sapiens with 17 samples.

How the data were processed

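Neurons were differentiated for 40 days from WT H9 cells and from KO lines KO1 and KO2. The labels list 17 samples: 8 RNA-seq libraries and 9 ChIP-seq samples, which are H3K27me3, H3K36me3 and a control for each of the 3 lines. The control is called input in the sample names, while its antibody label is normal rabbit IgG. The labels call the RNA libraries biological replicates and do not say whether replicates came from separate differentiations, so p-values measure only the spread between these libraries.

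Per the labels, the authors quantified RNA with Salmon 1.1.0 against GRCh38 and tested it with DESeq2 1.26.0. The deposited RNA table holds estimated counts per gene symbol, with fractional values and no normalization. The annotation and the step from transcripts to genes are not given in the sources used here. The authors' deposited table of KO against WT gives log2 fold changes with their standard errors, a score that is the Wald statistic, a p-value and an adjusted p-value, set to 1 where none was computed. Per the labels, the authors aligned ChIP reads with Bowtie2 2.4.1. Per the file headers, the authors called narrow peaks with MACS2 2.2.7.1 at a q of 0.01 from 1 treatment and 1 control alignment, keeping 1 tag per position. The deposited peak lists give the pileup signal at the summit, the fold ratio over the control and the -log10 q-value, all as the authors' own values. Coordinates are 1-based.

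Counts were rounded. The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, a quasi-likelihood F-test and Benjamini-Hochberg adjustment, with a threshold of FDR 0.05. KO against WT pooled both KO lines, and a fit with 3 groups gave KO1 against WT, KO2 against WT and KO2 against KO1. These tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. DESeq2 1.42.0 was fixed as a comparison tool, and its KO against WT fold changes lay within 0.001 of the authors' deposited log2 fold changes for 99.99% of 35365 genes. CPM values are TMM-scaled with SD across libraries. The 32 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and with an estimated correlation, and list means also by an exact permutation test. KDM6A is in 2 lists, and S100B, SOX10 and TTR are among the other genes in 2 lists. The lists cover the COMPASS complex, PRC2, demethylases and methyltransferases, neuronal, synaptic, ion channel, guidance, progenitor, proliferation, pluripotency, transmitter, regional and HOX genes, markers of glia and other lineages, non-neural regulators, signalling ligands, p53 targets, stress, hypoxia, mitochondrial, histone and imprinted genes.

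On simulated data with 200 changed genes, edgeR recovered 7.5%, 73.1% and 93.9% of genes changed 2-, 4- and 8-fold in the KO against WT design with 5 false calls, and DESeq2 38.8%, 86.6% and 95.5% with 76 false calls. In the KO1 design edgeR recovered 1.5%, 55.2% and 83.3%, and in the KO2 design 1.5%, 32.8% and 71.2%. DESeq2 made 81 false calls in the KO1 design and 97 in the KO2 design. The simulated libraries were drawn independently and lack the difference of KO1 replicate 2 and both KO2 libraries from the rest. These recovery shares therefore need not hold for the real libraries, and 0 real edgeR calls do not show that large changes were absent. Library totals of 17.4 to 31.5 M limit the precision of weakly expressed genes.

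Peaks were compared with bedtools 2.31.1 at an overlap of at least 1 bp. The annotation at hand (GRCh38.p14) has no strand, so the planned promoter, 2 kb around a start site, was replaced by 2 kb around either end of a gene, a departure from the plan. H3K36me3 was assigned by overlap with the gene span, and 2880 tested genes had no position. Classes were compared with RNA by camera and Fisher's exact test, two-sided.

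The planned naming rule required a call in every edgeR comparison and gave 0 genes. Genes were therefore named, after values were seen, from the authors' deposited table (12 largest increases and decreases among 890 candidates), from the 10 lowest edgeR p-values, from list members and from the genes of the longest peaks and of the peak classes, where DESeq2 calls stood in because edgeR made none. CDKN2B, ADM and the genes given with leave-out values were also chosen after their values were seen. Some genes that meet these rules are not reported here.

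Other settings fixed in advance were RLE scaling, other filters, DESeq2, a fold threshold, a replicate block, each library left out in turn, a 3-group contrast, stricter peaks, longer peaks, other overlaps and other windows. Added after seeing the data were leaving out the 3 high-collagen libraries (KO1 replicate 2 and both KO2 libraries), the mesenchymal list mean as a covariate, a robust fit, voom with sample weights, DESeq2 with each library left out, and the whole gene span. Leaving out those libraries also leaves no KO2 library. Raw reads were not analysed here.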

Results

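RNA and histone marks were measured in neurons grown to day 40 from H9 cells, an established human embryonic stem cell line, with or without a knockout of UTX (gene symbol KDM6A). UTX is a demethylase that removes methyl groups from lysine 27 of histone H3 and is a subunit of a COMPASS-type methyltransferase complex that acts at enhancers. The study's title names neural differentiation, the shape of dendrites, and promoters that carry activating and repressive marks together. PolyA RNA was sequenced from 3 wild-type (WT) libraries and 5 knockout (KO) libraries, 3 from line KO1 and 2 from line KO2. Totals were 23.9, 27.8 and 17.4 M estimated counts in WT (M for mega), 18.7, 21.6 and 31.5 M in KO1, and 23.3 and 21.5 M in KO2. ChIP had 1 library per line for H3K27me3, a mark of Polycomb-repressed chromatin, and for H3K36me3, a mark of transcribed gene bodies. Each mark had 1 deposited peak list per genotype, so no peak comparison has a replicate check.

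KDM6A RNA (X, 44873188 to 45112779, GRCh38) was measured at 36, 35.9 and 35.2 counts per M (CPM) in WT, 40.8, 30.1 and 34.1 in KO1, and 25.9 and 33.9 in KO2. The means were 35.7 ± 0.457 (SD, n = 3) in WT and 33.0 ± 5.50 (SD, n = 5) in KO, with an edgeR FDR of 0.672 and an adjusted p of 0.766 in the authors' deposited table. A count over the whole gene does not detect a small deletion or frameshift, and the edited position is not given in the sources used here, so these levels do not check the genotype labels.

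The libraries did not part by genotype alone. The first principal component held 59.9% of the variance and set KO1 replicate 2 (129.7), KO2 replicate 1 (79.7) and KO2 replicate 2 (77.5) apart from the other 5 libraries (-84.3 to -33.6). The same 3 libraries had high RNA of COL1A1, a fibrillar collagen chain made by connective tissue cells: 27540, 9226 and 14460 CPM, against 277.9 and 258.1 CPM in the remaining KO libraries and 125.7, 7.65 and 387.1 CPM in WT. They are called the 3 high-collagen libraries here. COL1A1 was singled out after its values were seen.

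**Figure D1:**
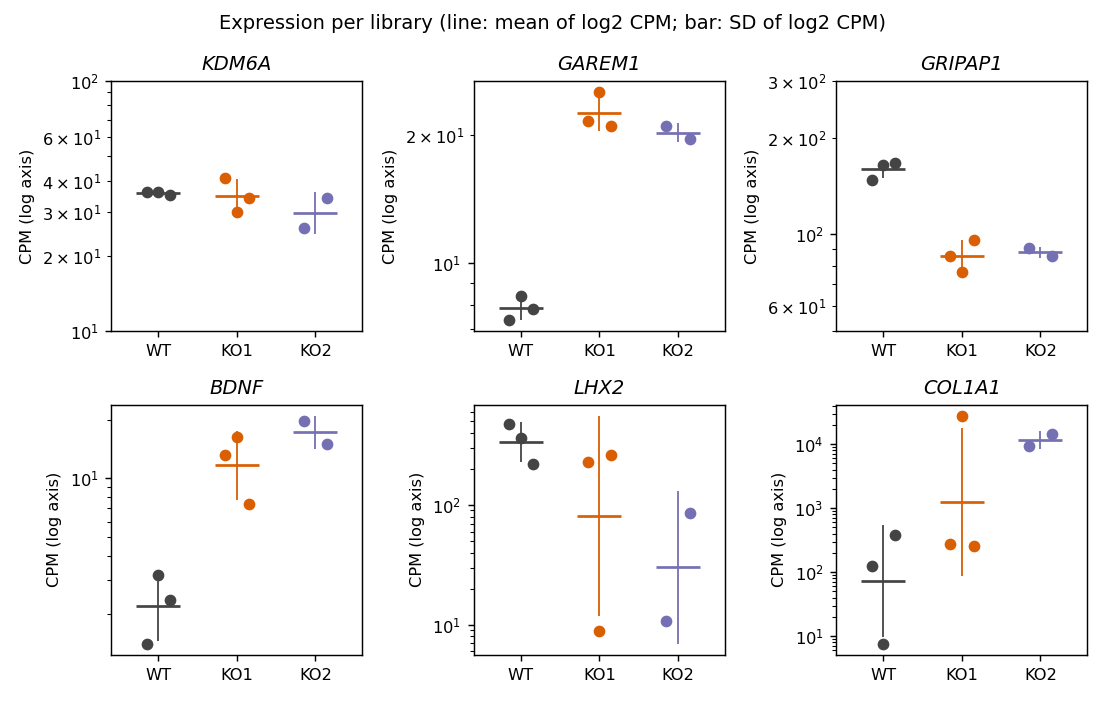
CPM on a log axis for KDM6A, GAREM1, GRIPAP1, BDNF, LHX2 and COL1A1, with a point per library (WT n = 3, KO1 n = 3, KO2 n = 2), a line for the mean and a bar for the SD of log2 CPM in each line. GAREM1, GRIPAP1 and BDNF parted WT from both KO lines, while LHX2 and COL1A1 differed more among the KO libraries.

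The first comparison asks which genes differed between UTX-KO and WT neurons. BDNF, a neurotrophin that acts on dendrites and synapses, rose from 2.32 ± 0.886 CPM (SD, n = 3) in WT to 14.3 ± 4.57 (SD, n = 5) in KO, with an adjusted p of 1.06e-07 in the authors' deposited table. GAREM1, an adaptor of growth factor receptor signalling (18, 32263522 to 32470882), rose from 7.86 ± 0.495 to 21.7 ± 2.11 CPM in the same table's test (adjusted p 7.65e-18). KITLG, the ligand of the KIT receptor, went from 24.4 ± 5.46 to 63.5 ± 10.6 CPM (adjusted p 1.69e-06). CDKN2B, an inhibitor of cyclin-dependent kinases 4 and 6, stood at 1.1 ± 0.244 CPM in WT and 31.2 ± 25.3 CPM in KO (adjusted p 7.09e-09).

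Fewer genes fell. GRIPAP1, which takes part in the recycling of AMPA receptors (X, 48973723 to 49002264), fell from 159.5 ± 10.1 to 86.9 ± 7.23 CPM (adjusted p 1.88e-10 in the authors' deposited table). P2RX3, an ATP-gated channel of sensory neurons, fell from 13.5 ± 5.93 to 2.09 ± 0.637 CPM (adjusted p 2.66e-08). LSM5, a subunit of an RNA-binding ring complex, went from 40.5 ± 1.5 to 21.5 ± 2.81 CPM and DYRK2, a protein kinase, from 117 ± 5.97 to 67.1 ± 8.57 CPM. SPINK5, a serine protease inhibitor, stood at 10.4 ± 1.49 CPM in WT and 0.701 ± 0.537 CPM in KO (adjusted p 6.98e-05). CRB1, an apical polarity protein, went from 29.3 ± 4.13 to 3.88 ± 3.74 CPM, TKTL1, a transketolase-like protein, from 20.8 ± 14.0 to 2.87 ± 2.06 CPM, and MPPED1 from 44.2 ± 3.99 to 10.7 ± 6.84 CPM.

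The largest increases in the authors' deposited table were in genes of connective tissue. MGP, a matrix protein that limits calcification, had a log2 fold change of 7.63 (SE 1.25), EGFL6 8.37 (SE 1.81), TNMD, a tendon glycoprotein, 7.16 (SE 1.17), COL8A2, a short-chain collagen, 7.40 (SE 1.75), and SMOC2, a matrix protein, 6.98 (SE 1.5). These genes followed the 3 high-collagen libraries: EGFL6 stood at 2933, 78.97 and 1025 CPM there and at 4.60 and 15.6 CPM in the remaining KO libraries.

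edgeR's quasi-likelihood test called 0 of 18614 genes at an FDR under 0.05, although 3337 genes had an unadjusted p under 0.05 (2137 higher and 1200 lower in KO; chance gives 931) and the smallest FDR was 0.0941, for GAREM1. DESeq2 called 1243 genes, 1003 higher and 240 lower, and these were the 1243 genes of the authors' deposited table. All 5 KO libraries lay above all 3 WT libraries in 1171 genes and below them in 1147, together 12.45% of the genes tested. The average over all 56 splits into 3 and 5 libraries is 3.57% for libraries without groups among them. This count was not repeated for other splits that keep the 3 high-collagen libraries together. The excess therefore does not measure an effect of the genotype. Without the 3 high-collagen libraries DESeq2 called 262 genes (161 higher, 101 lower), 150 of them among the 1243. BDNF, GAREM1, KITLG, CDKN2B, GRIPAP1, P2RX3, LSM5, DYRK2, SPINK5, CRB1, TKTL1 and MPPED1 were in both sets. The DESeq2 count was 590, 452 and 539 without WT replicate 1, 2 or 3. It was 776 and 2870 without KO1 replicate 2 or 3, and 749 and 590 without KO2 replicate 1 or 2.

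Genes of neuronal structure and synapses were mostly lower in KO. Of 25 pan-neuronal markers, 22 had a negative fold change (median log2 fold change -0.88; camera FDR 0.00231; adjusted p = 0.525 with an estimated correlation). CRMP1, which mediates semaphorin signalling in axons, stood at 730 ± 133 CPM in WT (SD, n = 3) and 436 ± 201 CPM in KO (SD, n = 5), and MAP2, the dendritic microtubule protein, at 955 ± 212 and 691 ± 448 CPM. No member passed edgeR over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 called 0. The list mean was 7.16 to 7.88 log2 CPM in WT, 7.35 and 7.54 in KO1 replicates 1 and 3, and 5.33, 6.94 and 6.20 in the 3 high-collagen libraries, without which its median was 0.01 (camera FDR 0.864). Without WT replicate 2 its FDR was 0.108.

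Of 26 synaptic vesicle and release genes, 23 had a negative fold change (median -0.73; camera FDR 0.00033; adjusted p = 0.498 with an estimated correlation). DESeq2 called 2 lower, edgeR called 0 over all genes and 0 adjusted over the list alone, and 3 had an unadjusted p under 0.05. CPLX1, a complexin that clamps vesicle fusion, went from 21 ± 4.71 to 6.65 ± 3.48 CPM (adjusted p 0.00517 in the authors' deposited table) and SYN3, a synapsin, from 26.4 ± 4.04 to 9.26 ± 4.71 CPM (adjusted p 0.0315). The list mean was 3.41, 5.06 and 4.10 log2 CPM in the 3 high-collagen libraries, against 4.96 to 5.64 in WT. KO2 replicate 1 (5.06) thus lay inside the WT range. Without the 3 libraries the list had a median of -0.03, and SYN3 was still lower by DESeq2 (log2 fold change -1.13, adjusted p 0.000992).

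Postsynaptic and dendritic genes had a median of -0.54 (29 of 37 negative; camera FDR 0.0216; adjusted p = 0.574 with an estimated correlation), and the list's FDR was 0.199, 0.0707 and 0.0639 without WT replicate 2, KO1 replicate 2 or KO2 replicate 2, with medians of -0.23, -0.24 and -0.40. BDNF rose, as given above, and CAMK2N1, an inhibitor of CaMKII, fell from 57.2 ± 11.2 to 32.2 ± 8.18 CPM (adjusted p 0.0346 in the authors' deposited table). edgeR called 0 members over all genes, and 1 (higher) passed when adjusted over the list alone. An unadjusted p under 0.05 was reached by 4 members, 3 lower and 1 higher. The median was 0.03 without the 3 high-collagen libraries. GABAergic markers had a median of -1.19 (12 of 15 negative; camera FDR 0.011; adjusted p = 0.498 with an estimated correlation). edgeR called 0 members over all genes, 1 (lower) adjusted over the list alone and 4 at an unadjusted p under 0.05. DESeq2 called 2 lower, among them SLC32A1, the vesicular GABA transporter. SLC32A1 varied among WT libraries (1.54, 18.3 and 15.3 CPM), as did DLX2, a regulator of interneurons (3.57, 42.2 and 44.8 CPM in WT). The GABAergic list had a median of -0.60 (FDR 0.171) without WT replicate 2 and of -0.47 without the 3 high-collagen libraries.

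Progenitor and cell division genes were lower in KO as well. All 24 proliferation genes had a negative fold change (median -0.67; camera FDR 1.6e-07; adjusted p = 0.498 with an estimated correlation), though edgeR called 0 over all genes, 0 adjusted over the list alone and 7 at an unadjusted p under 0.05, and DESeq2 called 0. MCM3 and MCM5, subunits of the replicative helicase, stood at 158 ± 10.3 and 113 ± 15.1 CPM in WT and at 108 ± 27.8 and 77.7 ± 18.2 CPM in KO, and CCNB2, a mitotic cyclin, at 71.2 ± 7.36 and 41.8 ± 15.7 CPM. Among 23 neural progenitor markers, 20 had a negative fold change (median -1.11, camera FDR 0.00119, adjusted p = 0.498 with an estimated correlation). There were 0 edgeR calls over all genes or adjusted over the list alone, and 0 DESeq2 calls. By edgeR 5 had an unadjusted p under 0.05, 4 lower and 1 higher. SOX3, a progenitor transcription factor, stood at 362 ± 75.3 CPM in WT and 75.9 ± 72.8 CPM in KO, NOTCH1, the receptor that keeps progenitors undifferentiated, at 457 ± 57.6 and 249 ± 110 CPM, and its ligand DLL1 at 179 ± 26.7 and 70.0 ± 57.0 CPM. The progenitor list mean was 7.54 to 7.60 log2 CPM in WT, 7.37 and 7.46 in KO1 replicates 1 and 3, and 5.28, 5.56 and 6.72 in the 3 high-collagen libraries. Without those libraries the median was -0.19 for proliferation genes (camera FDR 0.00523) and -0.23 for progenitor markers (camera FDR 0.2), and DESeq2 called SOX3 lower (log2 fold change -1.29, adjusted p 0.000316).

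Regional identity differed between cultures. Forebrain transcription factors had a median of -1.62 over 14 members but did not pass (camera FDR 0.21), with 0 calls by edgeR over all genes or adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2. The list mean was 6.01 to 6.41 log2 CPM in WT, 6.31, 3.56 and 6.45 in KO1, and 1.87 and 5.64 in KO2. EMX2, a regulator of cortical development, stood at 262 ± 97.8 CPM in WT and 112 ± 116 CPM in KO. Without the 3 high-collagen libraries the list's median was -0.06. HOX genes, which set identity along the body axis behind the midbrain, had a median of -1.70 over 15 members (camera FDR 0.00193; adjusted p = 0.498 with an estimated correlation). DESeq2 called 2 HOX genes lower, HOXC5 (log2 fold change -4.06, SE 1.1) and HOXB8 (-4.08, SE 1.22) in the authors' deposited table. edgeR called 0 HOX genes over all genes, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. The HOX list mean was 1.29, 3.46 and 3.54 log2 CPM in WT, 0.79, 1.05 and -1.5 in KO1, and 3.48 and 0.64 in KO2, so KO2 replicate 1 lay at the level of the 2 higher WT libraries. HOXB8 rested on WT replicate 2 (47.0 CPM, against 0.446 and 3.75 CPM in the other WT libraries). The HOX list's median was -2.81 without the 3 high-collagen libraries (camera FDR 6.04e-09) and -1.55 without KO1 replicate 3 (camera FDR 0.0503). Hindbrain, spinal and monoaminergic markers had a median of -0.10 and a mean difference of 0.04 (camera FDR 0.851), so the mean went against the median and the test's downward direction. DESeq2 called 2 of 21 higher, among them GATA2, a transcription factor of blood and interneuron lineages (0.744 ± 0.427 CPM in WT, 24.9 ± 22.8 CPM in KO). Glutamatergic markers (median -1.01; camera FDR 0.0763, but 0.0215 without WT replicate 3 and 0.0318 without KO1 replicate 1) and pluripotency markers (median -0.49; camera FDR 0.225) did not pass.

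Genes of connective tissue were higher in KO. All 22 mesenchymal and fibroblast markers had a positive fold change (median 3.11, 8.62-fold; camera FDR 1.75e-08; adjusted p = 0.498 with an estimated correlation). DESeq2 called 16 higher, and edgeR called 0 over all genes, 10 adjusted over the list alone and 17 at an unadjusted p under 0.05. TAGLN, a smooth muscle actin-binding protein, went from 11.6 ± 6.78 to 433 ± 280 CPM (adjusted p 1.63e-09 in the authors' deposited table), ACTA2, smooth muscle actin, from 10.1 ± 8.17 to 254 ± 158 CPM (adjusted p 1.69e-06), and FBN1, a microfibril protein, from 31.9 ± 11.4 to 405 ± 372 CPM (adjusted p 0.00117). The list mean was 10.15, 9.28 and 9.66 log2 CPM in the 3 high-collagen libraries, 5.97 and 5.78 in the remaining KO libraries and 5.34, 3.46 and 6.13 in WT. Without the 3 libraries the median was 0.62 (camera FDR 0.0221), and DESeq2 still called TAGLN higher (log2 fold change 3.97, adjusted p 0.00862).

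Of the lists for other cell lineages, 4 passed camera, while astrocyte, oligodendrocyte, endoderm and neural crest markers did not. Of 33 regulators of non-neural development, 30 had a positive fold change (median 2.45; camera FDR 1.78e-05; adjusted p = 0.498 with an estimated correlation), and DESeq2 called 14 higher. RUNX1 and RUNX2, regulators of blood and bone, stood at 0.366 ± 0.212 and 1.25 ± 0.310 CPM in WT and at 13.6 ± 11.1 and 16.7 ± 13.7 CPM in KO, and MSX2, a BMP-responsive regulator, at 3.94 ± 1.56 and 60.3 ± 47.9 CPM (adjusted p 2.1e-06, 0.000811 and 5.65e-05 in the authors' deposited table). Epithelial, choroid plexus and ciliated cell markers had a median of 1.48 (camera FDR 0.00033; adjusted p = 0.498 with an estimated correlation), and DESeq2 called 5 of 14 higher. CLDN6, a tight-junction protein of early epithelia, stood at 1.97 ± 0.816 CPM in WT and 12.3 ± 7.24 CPM in KO and KRT19, a simple-epithelium keratin, at 0.572 ± 0.436 and 10.9 ± 7.18 CPM. Endothelial and blood cell markers had a median of 1.57 (camera FDR 0.00193; adjusted p = 0.498 with an estimated correlation), and DESeq2 called 3 of 8 higher. KDR, a VEGF receptor, stood at 1.13 ± 0.462 and 24.6 ± 16.6 CPM. Muscle markers had a median of 0.53 (camera FDR 0.0413; adjusted p = 0.498 with an estimated correlation), and DESeq2 called 2 of 7 higher. The camera call ended without WT replicate 1, 2 or 3 (FDR 0.0783, 0.171 and 0.0839), KO1 replicate 1 or 2 (0.075 and 0.17), or KO2 replicate 1 or 2 (0.159 and 0.107). edgeR called 0 of the members of these lists over all genes and 3, 2, 3 and 0 adjusted over the list alone, with 17, 7, 3 and 2 at an unadjusted p under 0.05. Their means in the 3 high-collagen libraries were 3.05 to 3.64 (regulators), 2.45 to 4.38 (epithelial), 1.27 to 2.16 (endothelial) and 1.11 to 1.73 (muscle) log2 CPM, and their medians without those libraries were 0.32, 1.23, 1.59 and 0.18. KO1 replicate 1, inside the WT range for mesenchymal markers, had an epithelial mean of 3.17 and an endothelial mean of 0.88, above all WT libraries (0.66 to 1.99 and -1.0 to -0.46). KO1 replicate 3 had an epithelial mean of 1.78, inside the WT range, and an endothelial mean of -0.14.

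**Figure D2:**
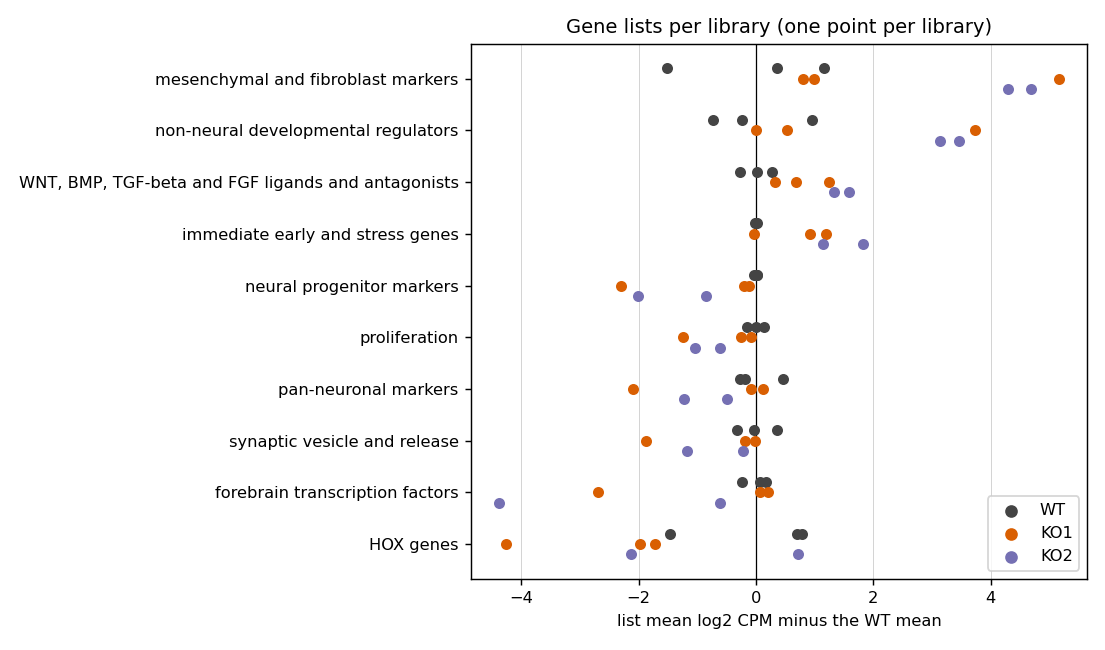
Mean log2 CPM of 10 gene lists in each library minus the WT mean, with a point per library (WT n = 3, KO1 n = 3, KO2 n = 2). Mesenchymal markers in KO1 replicate 2 and both KO2 libraries lay at 10.15, 9.28 and 9.66 log2 CPM, apart from 3.46 to 6.13 in the other 5 libraries, and the pan-neuronal list was lowest in KO1 replicate 2 (5.33).

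Signalling and guidance genes were higher in KO. Of 41 WNT, BMP, TGF-beta and FGF ligands and antagonists, DESeq2 called 11 higher and 1 lower (median 0.94, camera FDR 0.000406, adjusted p = 0.498 with an estimated correlation). edgeR called 0 over all genes, 9 adjusted over the list alone and 18 at an unadjusted p under 0.05 (16 higher, 2 lower). DKK2, a WNT antagonist, stood at 3.77 ± 2.54 CPM in WT and 193 ± 230 CPM in KO, TGFB2 at 16.1 ± 6.15 and 92.9 ± 53.2 CPM, and WNT7A, the ligand called lower, at 20.2 ± 18.5 and 4.78 ± 3.08 CPM. Of 35 axon guidance and adhesion genes, DESeq2 called 6 higher and 0 lower (median 0.48, camera FDR 0.0359, adjusted p = 0.498 with an estimated correlation). edgeR called 0 over all genes, 2 adjusted over the list alone and 13 at an unadjusted p under 0.05 (11 higher, 2 lower). SLIT2, a repellent of axons, rose from 162 ± 34.6 to 438 ± 118 CPM (adjusted p 0.000132 in the authors' deposited table), NRP1, a semaphorin co-receptor, from 40.7 ± 15.7 to 102 ± 16.0 CPM (adjusted p 0.000302). UNC5C, a netrin receptor, rose from 19.8 ± 8.60 to 69.9 ± 41.4 CPM (adjusted p 0.0126) and EFNA5, an ephrin ligand, from 32.3 ± 4.82 to 91.0 ± 51.8 CPM (adjusted p 0.0326). DESeq2 still called SLIT2 and NRP1 higher without the 3 high-collagen libraries (log2 fold changes 1.36 and 1.42), where the list medians were 0.38 for ligands and 0.30 for guidance. The guidance list's FDR was 0.0686, 0.0875 and 0.0802 without WT replicate 1, WT replicate 3 or KO1 replicate 3.

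Stress genes and transcripts of the mitochondrial genome were higher in KO. All 19 immediate early and stress genes had a positive fold change (median 0.85; camera FDR 0.000269; adjusted p = 0.498 with an estimated correlation), and DESeq2 called 5 higher. ATF3, a stress-induced transcription factor, rose from 10.3 ± 1.69 to 30.8 ± 18.5 CPM (adjusted p 0.0243 in the authors' deposited table) and FOSB, an immediate early factor, from 0.489 ± 0.151 to 3.42 ± 2.39 CPM (adjusted p 0.00223). HSPA5, a chaperone of the endoplasmic reticulum, stood at 307 ± 17.9 and 652 ± 274 CPM (adjusted p 0.0611). The 13 mitochondrially encoded mRNAs had a median of 0.30 (camera FDR 0.00193; adjusted p = 0.498 with an estimated correlation; 0 called by DESeq2), with MT-CYB at 2068 ± 247.3 and 3317 ± 793.1 CPM. The p53 target list had a median of 0.24 (camera FDR 0.0384; adjusted p = 0.498 with an estimated correlation; 3 of 18 higher by DESeq2), among them TP53I3, an oxidoreductase, at 16.2 ± 3.57 and 38.5 ± 13.1 CPM and FAS, the death receptor, at 2.46 ± 0.534 and 7.50 ± 4.08 CPM. That call ended without WT replicate 1 or 2, KO1 replicate 1 or 3, or KO2 replicate 1 (FDR 0.0721, 0.309, 0.0643, 0.072 and 0.0974). edgeR called 0 of the members of these 3 lists over all genes and 0, 0 and 3 adjusted over the list alone. At an unadjusted p under 0.05 the lists had 7, 4 and 4 members, all higher except 1 p53 target. Their means in the 3 high-collagen libraries were 4.64 to 5.32 (stress), 10.65 to 11.02 (mitochondrial) and 4.54 to 5.18 (p53) log2 CPM. In WT they were 3.48 to 3.52, 10.22 to 10.38 and 4.0 to 4.64. KO1 replicates 1 and 3 had 4.43 and 3.47 (stress), 10.44 and 10.4 (mitochondrial) and 4.75 and 4.55 (p53). All 3 means of KO1 replicate 1 and the mitochondrial mean of KO1 replicate 3 thus lay above all WT libraries. The p53 mean of KO1 replicate 2 lay inside the WT range. The list medians without the 3 high-collagen libraries were 0.15, 0.12 and 0.26.

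Chromatin regulators differed little. Genes of PRC2, which writes H3K27me3, had a median of -0.35 (camera FDR 0.0216; adjusted p = 0.498 with an estimated correlation), and 1 of 11 passed both DESeq2 and edgeR adjusted over the list alone (0 in edgeR over all genes, 2 at an unadjusted p under 0.05): PHF19, a PRC2-recruiting factor, went from 35.5 ± 0.959 to 26.8 ± 1.98 CPM (adjusted p 0.0188 in the authors' deposited table). The list had a median of -0.10 without the 3 high-collagen libraries and an FDR of 0.0784 without WT replicate 3. The COMPASS complex of UTX had a median of -0.19 (camera FDR 0.123), with PAXIP1 at 37.1 ± 1.25 and 31.2 ± 2.92 CPM. Demethylases and methyltransferases of lysines 27 and 36 had a median of -0.05 (camera FDR 0.243), with KDM6B, the other H3K27 demethylase, at 169 ± 29.0 and 130 ± 38.5 CPM and NSD2, an H3K36 methyltransferase, at 450 ± 18.2 and 294 ± 81.6 CPM. No member of either list passed edgeR over all genes, edgeR adjusted over the list alone, or DESeq2, and 1 and 2 had an unadjusted p under 0.05. The remaining lists did not pass camera: voltage-gated ion channels (median -0.63, FDR 0.339), astrocyte (0.75, 0.0729), oligodendrocyte lineage (0.42, 0.295), endoderm and liver (-0.10, 0.621), neural crest and peripheral glia (0.40, 0.0756), hypoxia and glycolysis (-0.03, 0.563), replication-dependent histones (-0.05, 0.621) and imprinted genes (0.15, 0.379). Astrocyte markers passed without WT replicate 1 or KO1 replicate 3 (FDR 0.00557 and 0.0445), and neural crest markers without WT replicate 3 or KO1 replicate 3 (0.0221 and 0.0182). For endoderm, hypoxia and histone genes the median was negative while the mean and the test pointed upward. DESeq2 called 3 astrocyte genes higher, among them GJA1, a gap junction protein (96.5 ± 54.4 and 486 ± 237 CPM), and 1 lower, FGFR3, a growth factor receptor (158 ± 95.1 and 51.9 ± 21.3 CPM).

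Camera thus called 18 of 32 lists, 10 higher and 8 lower, at its preset correlation and 0 with an estimated correlation (smallest unadjusted p 0.0421). An exact permutation test of the list means over the 56 splits of the libraries, two-sided, reached 0.0357 at the lowest, 0.218 after Benjamini-Hochberg adjustment over the lists, where 0.0179 is the smallest p possible. Without the 3 high-collagen libraries camera called 5 lists.

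The second comparison sets each KO line against the same WT libraries. edgeR called 0 genes for KO1 (1566 at an unadjusted p under 0.05) and 0 for KO2 (3566), while DESeq2 called 173 for KO1 (132 higher, 41 lower) and 839 for KO2 (646 higher, 193 lower). Without KO1 replicate 2, edgeR called 3228 genes for KO2 against WT, 2018 of them higher. By DESeq2, 119 genes were higher and 26 lower in both lines, among them BDNF (12.3 ± 4.56 CPM in KO1, n = 3, and 17.4 ± 3.32 CPM in KO2, n = 2), ACTA2, ADM, a vasodilator peptide, and ASIC1, an acid-sensing channel (29.1 ± 4.84 and 32.1 ± 6.13 CPM, against 56.5 ± 5.54 CPM in WT). Independent lists of these sizes would share 4.37 and 0.42 genes. Unchanged groups simulated against the same WT libraries shared 6.3 calls on average (1 to 11 in 20 simulations). edgeR's fold changes of the lines correlated at 0.839 across genes, which are not independent replicates, against 0.437 in the simulations, and their covariance was 1.01 against 0.164. The 3 WT libraries are too few to be split, so part of the excess may come from the shared controls. Simulated libraries were drawn independently, so they lack the RNA pattern that KO1 replicate 2 shares with both KO2 libraries. Its log2 CPM correlated at 0.932 and 0.97 with KO2 replicates 1 and 2, and at 0.875 and 0.865 with KO1 replicates 1 and 3. Part of the excess may therefore also come from these 3 high-collagen libraries rather than from the genotype.

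Mesenchymal markers had a median of 2.28 in KO1 and 4.33 in KO2 and non-neural regulators of 1.80 and 3.43, while proliferation genes (-0.53 and -0.82) and progenitor markers (-0.93 and -1.36) had negative medians. All 4 KO1 medians leaned on replicate 2. Its mesenchymal and non-neural means were 10.15 and 3.64 log2 CPM, while replicates 1 and 3 (5.97 and 5.78, 0.44 and -0.09) lay inside the WT range (3.46 to 6.13, -0.82 to 0.87). Its proliferation and progenitor means were 5.61 and 5.28, while replicates 1 and 3 (6.77 and 6.60, 7.37 and 7.46) lay inside or just below WT (6.71 to 7.0, 7.54 to 7.60). Camera called 16 lists for KO1 and 20 for KO2, and with an estimated correlation 0 for either (lowest adjusted p = 0.607 and 0.397). HOX genes were lower in KO1 (median -2.25; camera FDR 4.48e-07) and had a median of -0.90 in KO2 (camera FDR 0.228).

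Directly compared, KO2 and KO1 differed in 0 genes by edgeR (436 at an unadjusted p under 0.05) and in 9 by DESeq2. TRIM4, a ubiquitin ligase, stood at 5.24 ± 0.775 CPM in WT, 1.44 ± 0.315 CPM in KO1 and 5.18 ± 0.170 CPM in KO2 (DESeq2 adjusted p 0.000136 between the lines); it was named after its values were seen. Without KO1 replicate 2, edgeR called 958 genes between the lines.

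The third comparison asks where H3K27me3 was enriched in each genotype. Of the 5 longest peaks found only in the KO list, 1 lay at a progenitor list gene. A 10.69 kb KO peak on chromosome 15 (89359089 to 89369775) overlapped MIR9-3HG, a host gene of the neuronal microRNA miR-9, and a 7.73 kb KO peak on chromosome 9 (124011694 to 124019421) overlapped LHX2, a cortical selector gene. A 6.77 kb KO peak on chromosome 5 (88684208 to 88690974) overlapped MIR9-2HG, another host gene of miR-9, and MEF2C-AS2. A 5.20 kb KO peak next to it (88691686 to 88696883) overlapped MEF2C-AS2. A 6.98 kb KO peak on chromosome 15 (89405422 to 89412397) overlapped no protein-coding gene. The longest WT-only peak, of 4.30 kb on chromosome 3 (124883941 to 124888245), lay in ITGB5, an integrin subunit. The others lay in GFRA1, a GDNF co-receptor (10, 116269943 to 116272409), in COL18A1, a basement membrane collagen (21, 45404161 to 45406564), and at chromosome 6 27616193 to 27618658 and chromosome 9 64772947 to 64775320, which overlap no protein-coding gene.

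RNA of the genes under these peaks did not pass edgeR. MIR9-3HG stood at 232 ± 34.6 CPM in WT (n = 3) and 94.9 ± 58.4 CPM in KO (n = 5; edgeR FDR 0.259), and LHX2 at 352 ± 125 and 119 ± 120 CPM (FDR 0.41). LHX2 had 8.87, 10.7 and 85.4 CPM in the 3 high-collagen libraries and 230 and 262 CPM in the remaining KO libraries. ITGB5 rose from 16.3 ± 6.38 to 91.8 ± 66.8 CPM by DESeq2 (adjusted p 0.0115 in the authors' deposited table).

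The WT list held 10340 H3K27me3 peaks over 14.61 Mb and the KO list 10950 over 16.68 Mb. Of the KO peaks 59% overlapped a WT peak by at least 1 bp, and of the WT peaks 72.3% overlapped a KO peak. That left 4494 KO-only and 2867 WT-only peaks, with median lengths of 407 and 386 bp against 1158 and 875 bp for overlapping peaks. Of the 1000 peaks with the highest scores, 99.9% in WT and 99.8% in KO overlapped the other list. Both lists covered the HOX clusters: 103.7 kb of HOXA in WT and 105.5 kb in KO, 117.6 and 138.5 kb of HOXB, 112.7 and 115.0 kb of HOXC, and 95 and 98.2 kb of HOXD.

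Within 2 kb of a gene end, 39 of 39 HOX genes, 46 of 48 non-neural regulators and 17 of 17 GABAergic genes had an H3K27me3 peak in both lists. KO-only genes included the forebrain factor EMX2 (7.58 kb in 8 KO peaks), the Notch pathway genes DLL1 and HES5 with LHX2 and SOX9, a glial and progenitor factor (4 of 23 progenitor markers KO-only and 0 WT-only). They also included the neuronal genes INA, an intermediate filament, and NSG1, an endosomal protein, and the potassium channels KCNC1 and KCNH2 (4 of 26 channels KO-only and 0 WT-only). Other KO-only genes went the other way in RNA: JUNB, EGR1 and NR4A1 of the stress list and THY1 of the mesenchymal list. All 19 stress and all 22 mesenchymal members had a positive fold change in KO. WT-only genes included NRP1 (1.84 kb), UNC5C, ACTA2 and FBN1, which were higher in KO RNA by DESeq2. The KO list was called from 37.7 M tags and a control of 45.8 M, against 22.4 and 23 M in WT, so the lists differ in depth, and whether the KO list joins both KO lines is not given in the sources used here.

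**Figure D3:**
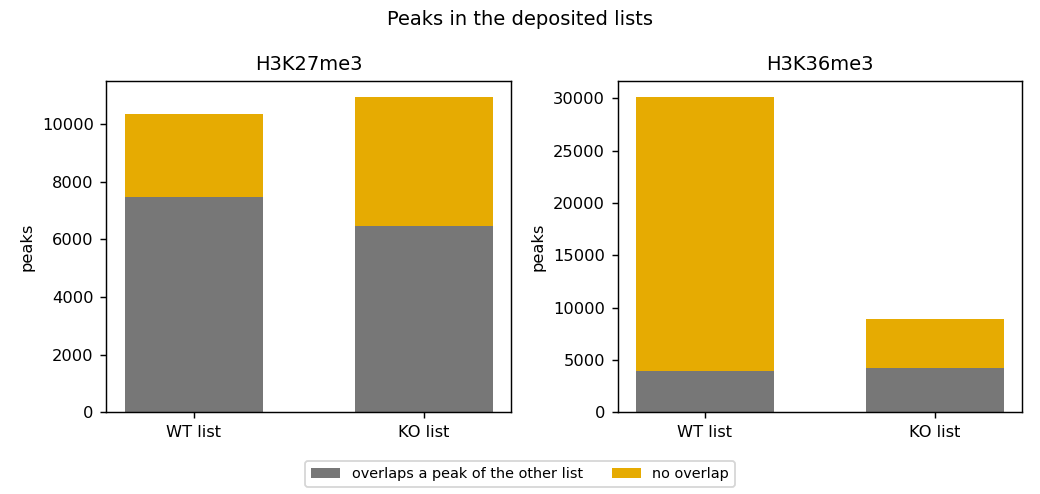
Number of peaks in the WT and KO lists of each mark, split into peaks that overlap a peak of the other list by at least 1 bp and peaks that do not (1 list per genotype, no error). The H3K27me3 lists were similar in length (10340 and 10950 peaks), and the H3K36me3 list was shorter in KO (30144 and 8937 peaks).

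H3K36me3 showed the opposite difference in list length. The WT list held 30144 peaks over 14.51 Mb with a median length of 382 bp, and the KO list 8937 over 2.64 Mb with a median of 254 bp. Of the KO peaks 47.7% overlapped a WT peak, and 13.2% of WT peaks overlapped a KO peak. The WT share was 4.4% when 50% of the peak had to overlap, 5.5% for stricter peaks and 3.7% for peaks of at least 500 bp on chromosomes 1 to 22 and X. A length minimum or a 50% overlap can lower this share because KO peaks were shorter. The stricter cutoff was the median score of both lists pooled (-log10 q 5.03), in which WT peaks outnumber KO peaks. These lower shares are therefore not separate evidence that fewer sites were shared. The longest WT-only peaks lay in APC2, a neuronal APC homologue (19, 1465205 to 1469274, 4.07 kb), CSNK1E, a casein kinase (22, 38295241 to 38299260, 4.02 kb), DAB2IP, a Ras GTPase-activating protein (9, 121772854 to 121776320), LAG3 and PTMS (12, 6769600 to 6773065) and DGCR8, a microRNA-processing factor (22, 20105721 to 20108657). The longest KO-only peaks were of 1.12 kb or less and lay in EEF1A1, a translation elongation factor (6, 73520072 to 73521196), ZNF557 (19, 7082865 to 7083939), SRSF3, a splicing factor (6, 36603127 to 36604060), DDX17, an RNA helicase (22, 38498400 to 38499301), and WDR82 (3, 52259254 to 52260116). In the KO list 96.6% of H3K36me3 peaks lay in protein-coding genes, and 96.3% in the WT list. Of the 1000 H3K36me3 peaks with the highest scores, 44.2% in WT and 62.7% in KO overlapped the other list. The KO H3K36me3 list was called from 44.4 M tags and the WT list from 22.5 M. Its fragment length was 200 bp in KO, equal to the preset length, and 269 bp in WT, so the lists also differ in this setting. For H3K27me3 it was 287 bp in KO and 290 bp in WT.

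The fourth comparison asks whether genes that gained or lost a listed H3K27me3 peak differed in RNA. Genes with a KO-only peak within 2 kb of a gene end were lower in KO: the 399 tested had a median log2 fold change of -0.31, 69.7% of them negative (camera FDR 0.000918; adjusted p = 0.366 with an estimated correlation). DESeq2 called 13 of 397 lower (3.27%), against 1.06% of genes without a peak in either list (Fisher's exact test, two-sided, odds ratio 3.15, p = 0.000568), while edgeR called 0 (49 at an unadjusted p under 0.05). DESeq2 called more of the class higher, 17 of 397 (4.28%, against 4.16%; p = 0.898 by the same exact test). Lower calls were also in excess among genes with a peak in both lists (46 of 2126, 2.16%; odds ratio 2.06, p = 6.85e-05 by the same exact test), so they were not particular to KO-only peaks. POU3F4, a neural POU-domain transcription factor, fell from 61.1 ± 28.1 to 15.2 ± 7.68 CPM (adjusted p 0.00795 in the authors' deposited table), GAREM2, a brain paralog of GAREM1, from 104 ± 4.83 to 41.4 ± 13.9 CPM (adjusted p 0.00311), ASIC1 from 56.5 ± 5.54 to 30.3 ± 4.88 CPM (adjusted p 0.000103), and CSPG5, a neural proteoglycan, from 31.4 ± 2.33 to 12.6 ± 5.61 CPM (adjusted p 0.0371). DESeq2 called these 4 genes lower also without the 3 high-collagen libraries, and the class had a median of -0.08 there (camera FDR 0.0434).

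Genes with a WT-only H3K27me3 peak were higher in KO (289 genes, median 0.53; camera FDR 3.32e-08; adjusted p = 0.366 with an estimated correlation). DESeq2 called 65 of 284 higher (22.9%, against 4.16% of genes with no peak, odds ratio 6.83, two-sided Fisher's exact p = 3.48e-28). edgeR called 0 (95 higher at an unadjusted p under 0.05). Exact tests of these classes treat genes as independent, while the inter-gene correlation estimated by camera was 0.161 in this class and 0.067 in the KO-only class. THBS1, a matrix glycoprotein, stood at 10.8 ± 6.69 CPM in WT and 696 ± 742 CPM in KO, and TPM2, a muscle tropomyosin, at 9.18 ± 5.90 and 191 ± 186 CPM. The class had a median of 0.19 without the 3 high-collagen libraries (camera FDR 0.0171). Among 2158 genes with a peak in both lists the median was 0.16 (camera FDR 0.0302, adjusted p = 0.366 with an estimated correlation). DESeq2 called 297 of 2126 higher (13.97%, odds ratio 3.74, p = 3.55e-58 by the same exact test), so the excess of higher calls was not particular to WT-only peaks. With the mesenchymal list mean as a covariate, the medians of the KO-only and WT-only classes were 0.0 and 0.06 and neither passed.

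Genes with H3K36me3 only in the WT list did not shift in RNA as a class (3539 genes, median -0.04; camera FDR 0.337). DESeq2 called 54 of 3536 lower, against 26 of 3325 genes with a peak in both lists (odds ratio 1.97, two-sided Fisher's exact p = 0.00465), and edgeR called 0 in either class (277 and 261 lower at an unadjusted p under 0.05). Genes with no H3K36me3 peak in either list were called lower at a similar rate (117 of 8410, 1.39%, against 1.53% of the WT-only class; odds ratio 1.79 to genes with both, two-sided Fisher's exact p = 0.00654), so the excess was not tied to a peak found only in WT. FGFR3, SYN3 and GAREM2 were among the 54, as was ID4, an inhibitor of bHLH transcription factors, which fell from 839 ± 105 to 314 ± 171 CPM (adjusted p 0.033 in the authors' deposited table). PPIEL, which shares sequence with related genes and is therefore uncertain, went from 15.5 ± 1.74 to 4.24 ± 1.03 CPM.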

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

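All tests of explanations in this part were chosen only after the result was seen.

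Among the named genes, 6 had 1 KO library far from the other 4, where 135 groups were tested and chance gives about 6.8. KO2 replicate 1 stood apart for DKK2 (595 CPM, others 11.2 to 142), CD44 (217, others 7.34 to 37.7), FAS (14.5, others 4.05 to 6.97) and KRT8, a simple-epithelium keratin (223, others 7.96 to 37.8). KO1 replicate 3 stood apart for KMT2C, a methyltransferase (198, others 151 to 158), and KO1 replicate 1 for NRP1 (129, others 89.0 to 100).

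The KO lines differed from each other in 16 lists by camera at its preset correlation and in 0 with an estimated correlation (lowest adjusted p = 0.497). The median log2 difference, KO2 minus KO1, was 2.02 for mesenchymal markers, 1.94 for non-neural regulators, 1.75 for HOX genes, 1.22 for epithelial markers, 1.14 for endothelial markers, 0.89 for hindbrain markers, 0.83 for signalling ligands, 0.67 for stress genes, 0.63 for astrocyte markers and 0.32 for mitochondrial mRNAs. It was -1.88 for forebrain factors, -1.02 for pluripotency markers, -0.47 for progenitor markers, -0.31 for proliferation genes, -0.19 for PRC2 and -0.17 for demethylases and methyltransferases. KO2 has only 2 libraries, both with high collagen RNA, so line and culture cannot be separated.

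The lower pan-neuronal RNA in KO was weighed first. The 10 most abundant genes can shift other genes by 0.16 log2 units at most, and 21 of 25 members lay below that shift, which argues against a few genes taking most of the counts. Without KO1 replicate 2 and both KO2 libraries the median was 0.01, so cells of another type in these 3 libraries are a candidate source. COL1A1 stood there at 9226 to 27540 CPM. The fall was uneven: the pan-neuronal mean was 5.33, 6.94 and 6.20 log2 CPM, against 7.16 to 7.88 in WT. In KO2 replicate 1 the synaptic and postsynaptic means (5.06 and 5.28) lay inside the WT range. Its ion channel mean (4.56) lay above all WT libraries, although its mesenchymal mean was 9.28. WT libraries express the mesenchymal list too, at a mean of 4.98 ± 1.37 log2 CPM (SD, n = 3). The 2 remaining KO libraries lay inside the WT range of the pan-neuronal list mean, and whether the UTX genotype made cells of another type more frequent stays open. Forebrain genes in KO2 replicate 1 fell by 3.89 log2 units beyond the pan-neuronal list (-4.38 against -0.49; SD of this difference among WT 0.28), which dilution alone does not give.

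The lower RNA of genes with a KO-only H3K27me3 peak was weighed next. The class median was -0.08 without the 3 high-collagen libraries, so cells of another type may give much of it, but the class still passed camera there. Of the KO-only peaks 22.6% scored above the median of the KO list, so deeper KO sequencing stays open for the weaker peaks. A biological origin in lost demethylase activity was not tested.

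The short KO H3K36me3 list was weighed last. The KO list was called from 1.97 times the tags of the WT list (control 1.98 times), which argues against fewer tags behind that list, while the depth of each KO library is not known because the list may join both KO lines. Of its peaks 96.6% lay in protein-coding genes, which argues against background noise. The highest fold enrichment was 7.5 in KO and 12.0 in WT, and the KO fragment length equalled the preset 200 bp (269 bp in WT). Both values go with weaker enrichment in the KO ChIP. It cannot be told apart from a loss of the mark, because each line has 1 library.

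Other splits of the 8 libraries into 3 and 5 were counted. The DESeq2 calls reached a share under 0.05 (2 of 56 splits as large, real 1243, highest other 6905). So did genes at an unadjusted p under 0.05 (2 of 56, 3337 and 8014). The shares were not adjusted for the several results counted on the same splits. Setting WT replicates 2 and 3 with KO1 replicate 3 against the rest gave 1228 and 3258, and also kept the 3 high-collagen libraries together. Counts near the real ones thus arose from a split other than the genotype, so these shares do not exclude chance. A share under 0.05 was not reached by the called lists (5 of 56, 18 and 21) or the mesenchymal list median (3 of 56, 3.11 and 4.26). Nor was it reached by the KO-only H3K27me3 class (3 of 56, 0.38 and 0.533) or the WT-only H3K27me3 class (4 of 56, 0.671 and 0.887). The WT-only H3K36me3 class did not reach it either (3 of 56, 0.155 and 0.182). edgeR called 0 genes in the real split (3337 at an unadjusted p under 0.05; DESeq2 1243) and at most 5665 in another, so all 56 splits are as large by construction and the count says nothing about chance. The split with 6905 calls sets the 3 high-collagen libraries against the rest and points to a structure of the samples. For KO1 against WT, fitted here without the KO2 libraries and so with other counts than in the 3-group fit, the 10 splits are too few for a share under 0.05. DESeq2 gave 152 in the real split and at most 99 in the others, 1 split as large. edgeR gave 0 in all 10 (1184 at an unadjusted p under 0.05 in the real split), which carries no information.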

How the results depend on the processing

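The tests that leave out the 3 high-collagen libraries, use the mesenchymal covariate, a robust fit, voom, the whole gene span or DESeq2 with libraries left out were chosen only after the results were seen; the others were planned. For lists, 408 list values kept direction and side of the threshold, 67 lost and 8 gained a call, and 28 changed direction. Single named genes gave 1755, 0, 70 and 9. The main edgeR setting called 0 genes, so no named gene could lose a call. The 1755 are values that stayed uncalled in the same direction, which is no sign of robust calls. Where a value below differs, the cause was not tested.

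edgeR's counts of 0 became, with DESeq2, 1243 (KO against WT), 173 (KO1), 839 (KO2), 9 (KO2 against KO1) and 145 (both lines). Sample weights in voom gave 3 for KO against WT, and no filter gave 1 for KO1 and 1 for KO2. Leaving out a library gave 0 to 3228 for KO2 and 0 to 958 for KO2 against KO1, both highs without KO1 replicate 2. The DESeq2 count for KO against WT ranged from 452 (without WT replicate 2) to 2870 (without KO1 replicate 3), and was 262 without the 3 high-collagen libraries. The replicate block gave 0 edgeR calls (2365 at an unadjusted p under 0.05; DESeq2 without it 1243), and equal replicate numbers did not pair the libraries.

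Counted over all 32 lists in each setting, camera called 18 in the main setting, 5 without the 3 libraries, 3 with the covariate and 0 with an estimated correlation. The covariate is the mean of the mesenchymal list, which was itself among the lists counted. Without the 3 libraries the median was 0.03 for postsynaptic, 0.13 for pluripotency, 0.23 for glutamatergic, 0.0 for hindbrain, -0.06 for forebrain and -0.2 for neural crest genes; for hindbrain and forebrain the test pointed upward. With the covariate it was 0.0 for demethylases, 0.46 for pan-neuronal, 0.28 for synaptic, 0.25 for postsynaptic, 0.09 for ion channel, 0.12 for pluripotency, 0.44 for glutamatergic, 0.06 for hindbrain, 0.12 for forebrain, -0.47 for non-neural, -0.06 for oligodendrocyte, 0.59 for endoderm and -0.63 for neural crest genes. Leaving out a library gave -0.46 to 0.49 for hindbrain, -0.13 to 0.15 for hypoxia and -0.21 to 0.29 for histone genes, and the 3-group contrast 0.01 for hindbrain and -0.18 for histone genes. Single genes turned without the 3 libraries (KDM6A 0.07, MAP2 0.22, INA 0.05) and with the covariate (KDM6A 0.08, MAP2 0.6, CRMP1 0.03, INA 0.52, EMX2 0.08, GFRA1 -0.23), none of them called.

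The KO-only H3K27me3 class had a median of 0.0 with the covariate and stayed at -0.31 without a call with an estimated correlation. The class with H3K36me3 in both lists had 0.0 with the covariate. The share of KO H3K27me3 peaks that overlap WT was 59%, and 44.7% when 50% of the peak had to overlap, 68.4% for stricter peaks and 66.6% for peaks of at least 500 bp on chromosomes 1 to 22 and X. For H3K36me3 it was 47.7%, and 37.7%, 44.4% and 59.1%. The share of WT peaks that overlap KO moved from 72.3% to 61.5%, 80% and 79.2% for H3K27me3 and from 13.2% to 4.4%, 5.5% and 3.7% for H3K36me3.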
